A study of Mus musculus with 5 samples.

How the data were processed

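The samples were bone marrow-cultured mast cells of C57BL/6 mice, 2 of the Cpa3-Cre genotype and 3 of the Cpa3-Cre;miR-9∆fl/∆fl genotype, grouped by their titles. Per the labels' protocols, cells were kept for 6 to 8 weeks in medium with 50 ng/mL recombinant interleukin-3, RNA was treated with heparinase, ribosomal RNA was depleted, and strand-marked total RNA libraries were sequenced on an Illumina HiSeq instrument as paired 50-base reads, about 70000000 per sample. Nothing in the labels says that samples of a group came from separate mice or cultures, so the p-values measure the spread between these samples, which may be technical.

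The data were a single table of 25549 gene models. Per the submitters' processing notes, STAR, HTSeq, DESeq2, Cuffdiff and DESeq were used with GRCm38 and mm10, without versions or roles, and per the labels' design text DESeq2 served for the statistics with a p-value threshold of 0.0001, although that text also names a one-way ANOVA. The authors deposited, per the file headers, a log2 fold change of the miR-9 line over the Cpa3-Cre control, the same fold on a signed linear scale, and a p-value per gene. The deposited signed fold equalled the power of 2 of the log2 value within 0.001 in 100 percent of rows. The model formula, the filters, the use of strand in counting, and whether the log2 fold changes were shrunken towards 0 are not given in the sources used here; shrinkage would make the folds of scarce or variable genes too small. The p-value was deposited for 24071 rows and is empty in 1478, and its spread over the range from 0 to 1 is that of unadjusted values. A gene length, the summed exon length, also comes with each row.

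The table also holds 5 columns of values per library, whose names match no sample's labels, so none was used in any step. Tests of expression per sample, standard errors, principal components, leave-one-out fits and abundance filters were therefore not made, and no depth beyond the stated reads was used. Following the design fixed before the data were examined for a table of this kind, the authors' fold changes and p-values were used with no test of expression run here. Benjamini-Hochberg adjustment was applied to the 24071 deposited p-values with statsmodels 0.14.6, and genes with an adjusted p under 0.05 were called.

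Rows were matched to GENCODE M21 (GRCm38) by symbol and position (23695), or by position alone with at least 80 percent reciprocal overlap (1477); 377 had no match. Of the symbol matches, 89.4 percent began and ended within 1000 bases of the M21 gene. The match gave gene class, GC content, newer symbols and 3' UTRs. Symbols shared by several rows (43 symbols, 94 rows) were left out of lists, and 25 symbols had turned into calendar dates.

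Of 36 gene lists fixed in advance, 33 had at least 3 members with a p-value and were tested; neutrophil markers, eosinophil markers and the miR-9 loci were not. The planned list test on log2 CPM was not run, since those columns were not used; cameraPR of limma 3.58.1 in R 4.3.3 was run on signed normal scores made from the deposited p-value and the sign of the deposited log2 fold change, with an inter-gene correlation preset to 0.01 and adjustment over the 33 lists. It compares the members with all other genes. A rotation test and an estimated correlation need values per library and were not run. The sign of a list's median, mean and test differed for 6 lists: heparin synthesis, lipid mediators, degranulation, integrins, unfolded protein and amino acid stress, and sex-linked genes.

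For the seed test, each gene's longest M21 3' UTR was searched for the 7-base site, log2 fold changes were adjusted by a linear fit on log2 UTR length and GC content, and the difference of medians between genes with and without a site was compared with that of all orders of the same bases. Counts of rows without a p-value were compared by two-sided Fisher's exact tests, and neighbouring called genes with 10000 random placements. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

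Named genes were the 12 largest rises and the 12 largest falls among called protein-coding genes with a proper symbol; Cma1, Cpa3, Kit, Fcer1a, Tpsb2, Mcpt4 and the miR-9 loci in any case; up to 4 called members with the smallest adjusted p of each list that passed or had 3 called members; and sex-linked genes. The rule also asked for a mean of 1 CPM and for groups that do not overlap, which were not applied because the values per library were not used. Other list members are named as examples and were chosen after their values were seen.

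The steps were tested on simulated data. Among 24071 simulated scores with 200 shifted, the adjustment called 65.5 percent of those shifted by 4 standard normal units, 93 percent at 5 and 99.25 percent at 6. The list test found a shift of 1 in the cholesterol list in 17 of 20 runs and called 1 of 640 unshifted lists, with independent genes. A fall planted at -0.05 in the genes with a miR-9-5p site was returned as -0.0479 ± 0.0109 (SD of the simulated runs). Alternatives were the p-value threshold of 0.0001, protein-coding genes only, an adjusted p under 0.10, preset correlations of 0.05 and 0.1, the rank form of the list test, scores adjusted for gene length and GC content (known for 98.5 percent of tested rows), longer seed sites and no UTR adjustment.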

Results

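RNA was sequenced from bone marrow-cultured mast cells, which are mast cells grown out of mouse bone marrow in interleukin-3, from C57BL/6 mice of 2 genotypes. Control mice carried Cpa3-Cre, in which the promoter of the mast cell carboxypeptidase gene Cpa3 drives the Cre recombinase (n = 2 samples). The other mice carried Cpa3-Cre together with the miR-9∆fl/∆fl allele and are called the miR-9 line here (n = 3 samples). The labels do not say whether recombination raises or removes miR-9, a microRNA encoded at 3 loci (Mir9-1, Mir9-2 and Mir9-3). Cells had been cultured for 6 to 8 weeks, and total RNA without ribosomal RNA was read as paired 50-base reads at a stated depth of about 70000000 reads per sample. The comparison asks which transcripts differ between the genotypes, and the series title singles out Cma1, the mast cell chymase. All fold changes and unadjusted p-values are those of the authors' deposited table, with positive values where the miR-9 line is higher. The standard error and depth behind each gene, and how many samples share its direction, were not analysed here.

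The strongest change in the miR-9 line lay at a miR-9 hairpin. Gm25641, a microRNA-class gene model of 1 exon and 108 bases, covers the Mir9-1 hairpin on chromosome 3. In the authors' deposited table Gm25641 rose by a log2 fold change of 4.50, or 22.6-fold, with p = 3.63e-22, the smallest p-value of all genes. Its Benjamini-Hochberg adjusted p, computed here from the authors' deposited table, was 8.74e-18. The transcripts that host the 3 hairpins did not pass the test. Gm3764, a long noncoding RNA of 12 exons with the Mir9-1 hairpin in an intron, had a log2 fold change of -0.15 in the authors' deposited table (p = 0.771). AI854517, which by position is the host of Mir9-3 and carries its hairpin in an intron, stood at -1.06 in the authors' deposited table (p = 0.0339, adjusted p = 0.553). C130071C03Rik, which holds the Mir9-2 hairpin in an exon, stood at -0.61 in the authors' deposited table (p = 0.168, adjusted p = 0.799). In GRCm38 coordinates, Gm25641 spans 88215589 to 88215696 on the minus strand and the hairpin spans 88215598 to 88215686 on the plus strand. Gm3764 also lies on the plus strand, so it hosts the hairpin and is antisense to Gm25641. Whether counting used strand is not given in the sources used here, so reads of the hairpin strand and of the opposite strand are not told apart, and 50-base total RNA libraries do not measure the mature microRNA.

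**Figure D1:**
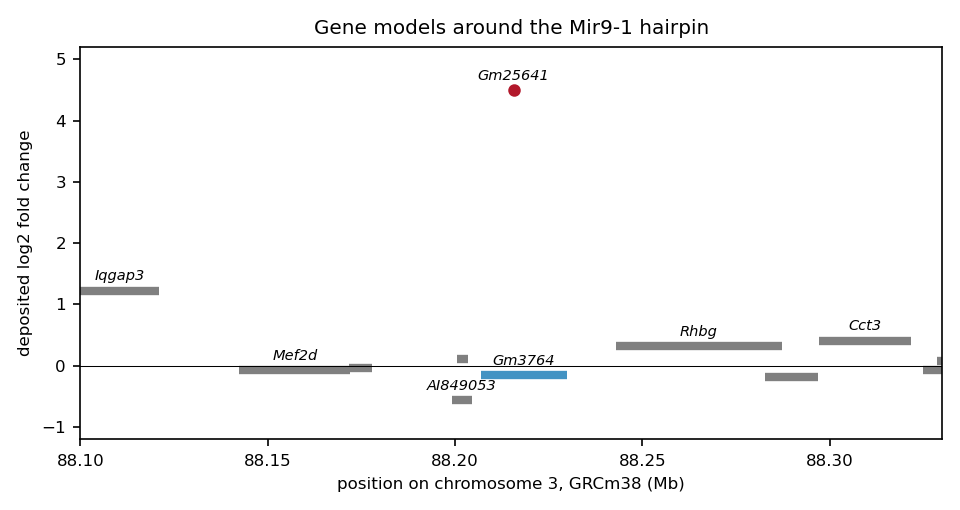
Gene models around the Mir9-1 hairpin, with position on chromosome 3 (GRCm38, Mb) on the x axis and the log2 fold change of the authors' deposited table, miR-9 line over Cpa3-Cre, on the y axis. Each bar spans a gene model. Gm25641 (red point, minus strand) stands at 4.50, and Gm3764 (blue, plus strand), the host of the hairpin, at -0.15.

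Across the transcriptome, 59 genes rose and 40 fell in the miR-9 line at an adjusted p-value under 0.05, out of 24071 genes with a p-value in the authors' deposited table. At an unadjusted p under 0.05 the balance was the other way, with 931 higher and 975 lower, and 40.2 percent of all genes with a p-value in the authors' deposited table had positive values. Of the 99 genes, 27 missed the threshold of 0.0001 named in the design text. The largest rises among called protein-coding genes, leaving out predicted gene models, were in Tpsg1, a transmembrane tryptase (log2 fold change 2.58 in the authors' deposited table), and its neighbour Cacna1h, a T-type calcium channel (2.26). Scd1, the stearoyl-CoA desaturase, rose by 2.22 and Slco2b1, an organic anion transporter, by 2.15 in the authors' deposited table. Gm4980, near Slco2b1 on chromosome 7, was left out of this ranking by its symbol, although GENCODE M21 names it Tpbgl. This protein-coding gene rose by 2.26 in the authors' deposited table (adjusted p = 0.000105). Fyn, a Src-family kinase that acts downstream of the IgE receptor, rose by 1.97 in the authors' deposited table (3.91-fold, adjusted p = 0.00375). The other large rises in the authors' deposited table were Nt5dc2 (1.83), the histone gene Hist1h2bb (1.79), the desmosomal gene Pkp1 (1.77), Pvrl1, which encodes nectin-1 (1.76), the mitotic genes Cdc25c (1.69) and Ckap2l (1.69), and the acyl-CoA synthetase gene Acsbg1 (1.68).

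The largest fall among called genes was in Gpr65, a proton-sensing receptor, at a log2 fold change of -2.65 in the authors' deposited table (6.27-fold lower, adjusted p = 9.87e-08). Galc, the lysosomal galactosylceramidase gene beside it on chromosome 12, stood at -2.16 in the authors' deposited table (adjusted p = 1.00e-08). Large falls in the authors' deposited table also included Gucy1a3, a subunit of soluble guanylate cyclase (-2.59), the Src-family kinase gene Fgr (-2.50), the lysophosphatidic acid receptor gene Lpar4 (-2.43) and the Slit receptor gene Robo1 (-2.11). Hs3st5, a heparan sulfate sulfotransferase, fell by 2.58 on the log2 scale in the authors' deposited table. Triqk (-2.32), Thsd1 (-2.32), Gimap3 (-2.25), the Y-linked Srsy (-2.15) and Apol9b (-2.11) completed the 12 largest falls in the authors' deposited table. The ranking was again among called protein-coding genes, leaving out predicted gene models. Tpsg1 and Cacna1h overlap by 158 bases, and Srsy, Apol9b, Gimap3, Hist1h2bb and the tryptases have close relatives, so their values are uncertain where reads were shared. At an adjusted p under 0.10, a threshold chosen after the data were seen, 233 genes passed, 165 higher and 68 lower.

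**Figure D2:**
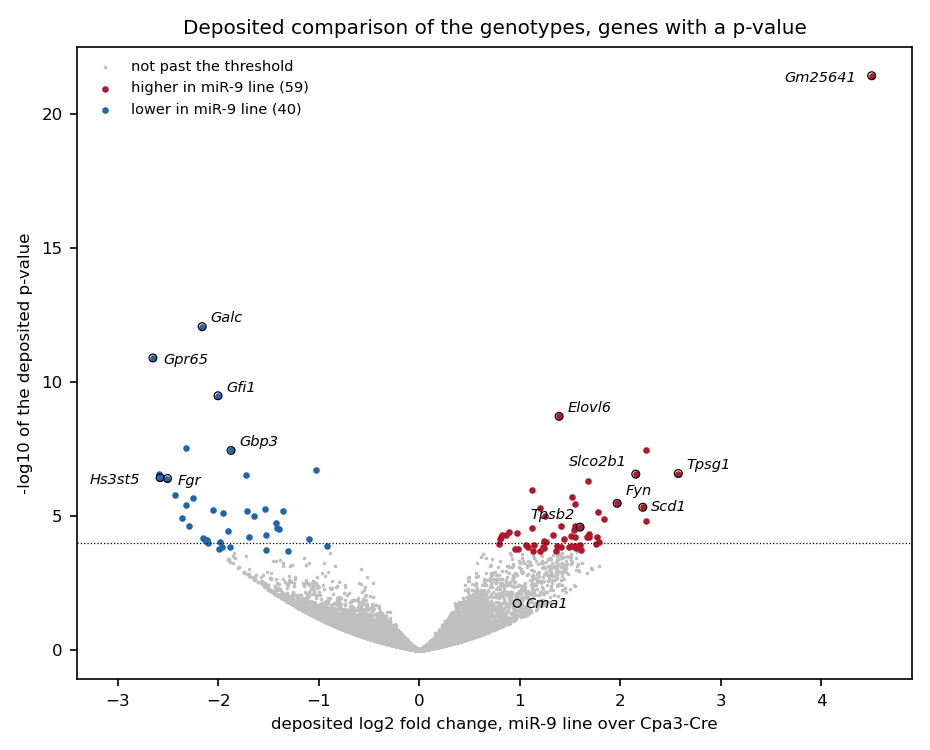
Log2 fold change of the authors' deposited table, miR-9 line over Cpa3-Cre (x axis), against -log10 of its p-value (y axis), 1 point per gene with a p-value. Red marks the 59 genes higher and blue the 40 genes lower, and the dotted line marks the p-value threshold of the series' design text. Open circles mark the genes labelled by name. Gm25641 lies apart at 4.50, and Cma1 lies among the genes that did not pass.

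Cma1 did not pass the test over all genes. Its log2 fold change in the authors' deposited table was 0.97, or 1.97-fold higher in the miR-9 line, with p = 0.0176 and an adjusted p of 0.442. The gene lies on chromosome 14 from 55941453 to 55944661 (GRCm38). Of the 11 granule protease genes with a p-value in the authors' deposited table, 9 had positive values, 2 rose (Tpsg1 and Tpsb2), none fell and 9 did not pass; 2 also passed when adjusted over the list alone. Tpsb2, the mast cell tryptase beta gene, rose by 1.60 in the authors' deposited table (3.03-fold, adjusted p = 0.0149). Cpa3 stood at 0.42 (p = 0.0983), Mcpt4, another chymase gene, at 0.47 (p = 0.379), and Tpsab1 at -0.12 in the authors' deposited table. As a group the proteases were higher than other genes, with a median of 0.47 and a list test adjusted p of 4.40e-07 computed from the authors' deposited table.

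Genes that define mast cells did not pass the test as a group. None of the 21 identity genes tested passed, over all genes or adjusted over the list alone; 1, Maob, had an unadjusted p under 0.05, and the median was 0.07 (limma list test, adjusted p = 0.170). Kit, the receptor of stem cell factor, stood at -0.04 (p = 0.910) and Fcer1a, the IgE-binding chain of the IgE receptor, at 0.09 (p = 0.815) in the authors' deposited table. Among 28 genes of IgE receptor and KIT signalling, Fyn alone passed, over all genes and adjusted over the list alone, and the list did not (adjusted p = 0.138). The lists of connective tissue type mast cell genes (median 0.12, adjusted p = 0.120), degranulation machinery (0.14, 0.498), heparin synthesis (0.02, 0.922), lipid mediator synthesis (0.16, 0.226) and mast cell cytokines (-0.35, 0.226) did not pass either. For degranulation, heparin and lipid mediators the mean had the opposite sign to the median and the test.

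Cell cycle genes were higher in the miR-9 line as a group. Of 31 tested, 29 had positive values in the authors' deposited table with a median of 1.22, 3 rose over all genes (Cdk1, Cdc25c and Rrm1), and 26 were higher when adjusted over the list alone. Cdk1, the mitotic kinase, rose by 1.55 and Rrm1, a subunit of ribonucleotide reductase, by 1.23 in the authors' deposited table, with adjusted p-values of 0.0245 and 0.0396. The proliferation marker Mki67 stood at 1.51 (adjusted p = 0.0560) and cyclin gene Ccna2 at 1.56 (adjusted p = 0.0657) in the authors' deposited table, while Ccnd1 (-0.35) and Ccnd3 (-0.02) were the 2 members with negative values. The replication-dependent histone genes, which are expressed in S phase, had positive values in 18 of 18 members with a median of 1.08 from the authors' deposited table. Hist1h2bb and Hist1h1b rose over all genes, the latter by 1.67 in the authors' deposited table, and 15 were higher when adjusted over the list alone. The list tests gave adjusted p-values of 1.15e-36 for the cell cycle and 7.89e-21 for the histones. With the inter-gene correlation preset to 0.1, these list test adjusted p-values were 2.69e-12 and 2.67e-09. A list test of this kind compares genes with genes, so its p-value does not measure how well the samples of a group agree.

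Genes of cholesterol synthesis were higher together. All 22 tested had positive values in the authors' deposited table, with a median of 1.02; 3 rose over all genes and 19 were higher when adjusted over the list alone (list test adjusted p = 4.92e-31). Sqle, the squalene epoxidase gene, rose by 1.12, Dhcr7, for the last reductase of the pathway, by 1.13 and Mvk, the mevalonate kinase gene, by 0.98 in the authors' deposited table. Hmgcs1 (1.33, adjusted p = 0.0883) and Fdps (1.44, adjusted p = 0.0932) stood as high in the authors' deposited table without passing. A list of fatty acid synthesis genes was chosen after the data were seen, so its test is a description. Its 14 members all had positive values in the authors' deposited table (median 0.79), and 3 rose: Scd1, the elongase gene Elovl6 (1.39, adjusted p = 8.95e-06) and the fatty acid synthase gene Fasn (1.20, adjusted p = 0.00476).

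**Figure D3:**
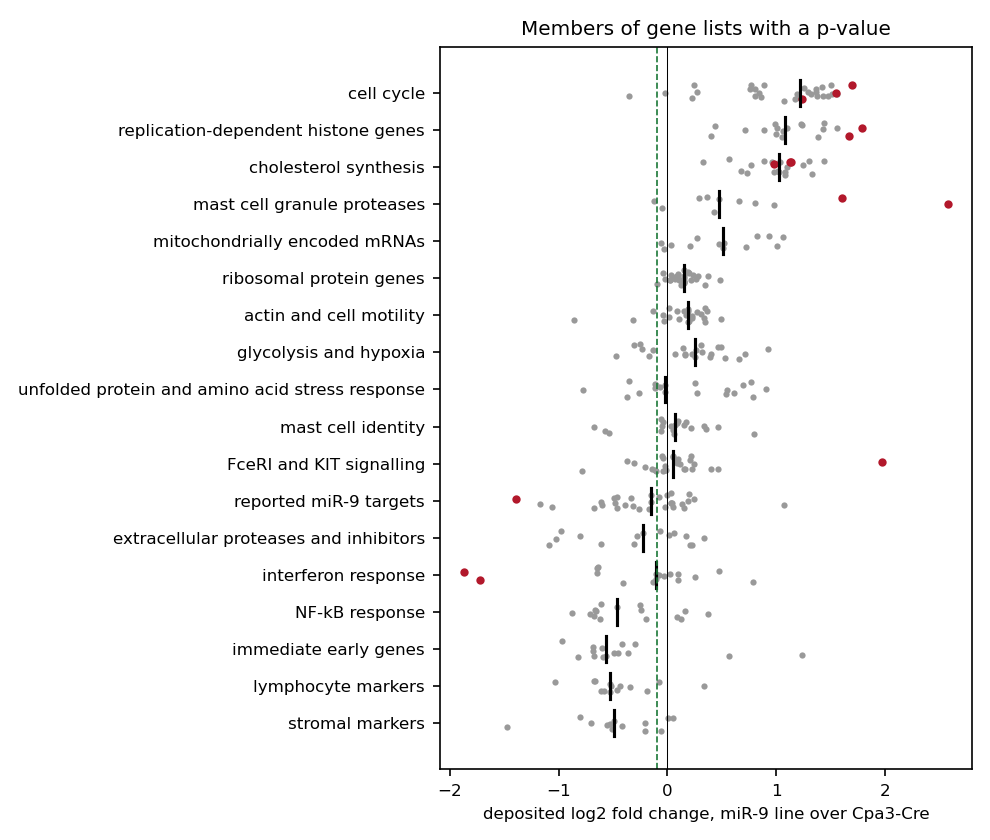
Log2 fold changes of the authors' deposited table, miR-9 line over Cpa3-Cre (x axis), for the members of 18 gene lists (y axis), 1 point per gene with a p-value. Red points passed an adjusted p-value of 0.05 over all genes, black bars are list medians and the dashed line is the median of all genes, -0.09; the cell cycle (1.22), histone (1.08) and cholesterol synthesis (1.02) medians lie farthest right.

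Mitochondrially encoded mRNAs were also higher as a group, with 11 of 13 positive values in the authors' deposited table and a median of 0.51 (list test adjusted p = 3.17e-05). No single one passed, over all genes or adjusted over the list alone; 3 had an unadjusted p under 0.05, led by mt-Nd6 at 1.06 in the authors' deposited table. Smaller group shifts were seen for ribosomal protein genes (median 0.15, adjusted p = 0.0184), actin and motility genes (0.19, 0.0122) and glycolysis genes (0.25, 0.0153), again with no single gene past the test over all genes or the list alone. The unfolded protein and amino acid stress list was called higher (adjusted p = 0.0112) although its median was -0.02, and its mean was 0.17. Its chaperone genes Sdf2l1 (0.91) and Calr (0.78) passed when adjusted over the list alone, and Ddit4, which restrains growth signalling, stood at -0.78 in the authors' deposited table. These 4 calls were lost at an inter-gene correlation preset to 0.05, with adjusted p-values of 0.157, 0.111, 0.111 and 0.0827 in the order given, while the 5 lists of proteases, cell cycle, histones, cholesterol synthesis and mitochondrial mRNAs passed there too. The stress list also missed by ranks (adjusted p = 0.0790). A correlation estimated from the libraries was not used here. Passing at a preset value therefore does not show that a list would pass at the true correlation of its members. This holds for the mitochondrial mRNAs, all encoded by a single genome, as for the other lists.

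Several immune and regulatory genes fell without their lists passing, and those named here were chosen after their values were seen. Gfi1, a transcriptional repressor of blood progenitors, fell by 2.00 on the log2 scale in the authors' deposited table (adjusted p = 1.91e-06, passing also over the list alone); it overlaps the gene model A430072P03Rik, which also fell. It was the 1 called gene of the 14 progenitor markers tested (list adjusted p = 0.170). The interferon-inducible GTPase genes Gbp3 (-1.87) and Gbp2 (-1.72) fell in the authors' deposited table, and the other 15 interferon response genes tested did not pass, over all genes or adjusted over the list alone (list adjusted p = 0.108). Of 31 reported miR-9 targets with a p-value in the authors' deposited table, 20 had negative values, where 59.8 percent of all genes with a p-value did. Lifr, a cytokine receptor subunit, alone passed, at -1.40 in the authors' deposited table (adjusted p = 0.0166). Adjusted over the list alone, 2 targets were lower (Lifr and Zc3h12a) and 1 higher (Stmn1), and the list test did not pass (median -0.15, adjusted p = 0.170). Over all genes, no member passed in the lists of NF-kB response (median -0.46, adjusted p = 0.0633), TGF-beta and EMT genes (-0.37, 0.0644), immediate early genes (-0.56, 0.108), extracellular proteases (-0.23, 0.348), integrins (0.01, 0.901), chemotactic receptors (0.24, 0.170) and structured noncoding RNAs (-0.09, 0.737), and neither did the lists. Adjusted over the list alone, Smad3 and Skil of the TGF-beta list and Itgb3 of the integrin list were lower, at -0.80, -1.02 and -0.84 in the authors' deposited table.

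To ask whether predicted targets shifted as a set, 16200 genes were searched for miR-9 seed matches in their longest annotated 3' UTR. The 2319 genes with a match to the miR-9-5p seed (ACCAAAG) differed from the others by a median of -0.00232 in log2 fold change after adjustment for UTR length and GC content. Among the 105 orders of the same bases, 68 gave a difference as low, the seed itself included. For miR-9-3p (AGCTTTA), 1989 genes had a match and the difference was 0.0230, with 268 of 420 orders as far from their median. A fall had to reach -0.0527 to enter the lowest 5 percent of orders for miR-9-5p, so smaller shifts could not pass this cut. Every order below that value holds the bases CG in a row, which the seed does not, with AACAACG lowest at -0.0963. Without CG the lowest order was GACACAA at -0.0493. The number of genes carrying each order was not taken into account.

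Markers of neutrophils, monocytes and eosinophils gave few values. Of the neutrophil markers 16 of 17, of the monocyte and macrophage markers 14 of 18 and of the eosinophil markers 8 of 10 had no p-value in the authors' deposited table, against 1478 of all 25549 rows. The 4 monocyte markers with a p-value had a median of -0.51 (list adjusted p = 0.350). Lymphocyte markers (median -0.52, adjusted p = 0.0598), stromal markers (-0.49, 0.0891), dendritic cell genes (-0.40, 0.170), basophil markers (-0.35, 0.581) and erythroid markers (0.01, 0.170) did not pass, with no member called. Adjusted over the list alone, 1 monocyte marker, Apoe, was lower (-1.31 in the authors' deposited table). The lymphocyte list passed with protein-coding genes only (adjusted p = 0.0444), after adjustment for gene length and GC (0.0475) and by ranks (0.0237), and the immediate early list passed by ranks (0.0234).

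Sex-linked genes were read as a check of the labels, which state matched sexes. Xist, which is expressed from the inactive X chromosome, stood at 1.58 in the authors' deposited table (p = 0.000994, adjusted p = 0.101), and Tsix at 0.40. Adjusted over the list alone, Xist passed, and the list of 6 genes did not (adjusted p = 0.569, median -0.28 and mean 0.04). The single-copy Y genes Uty (-0.65), Kdm5d (-0.55), Ddx3y (-0.36) and Eif2s3y (-0.20) did not pass in the authors' deposited table. Of 46 Y-linked rows with a p-value 39 were negative, where 59.8 percent of all genes with a p-value were, and 4 multicopy genes fell. Whether the groups match in sex is not settled by these values, since the values per library were not used.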

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

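The adjusted p threshold of 0.10 and all alternatives to the list test were chosen after the data were seen. At an adjusted p under 0.10, 233 genes passed, 165 higher and 68 lower, against 99, 59 and 40, as the looser threshold requires. At p under 0.0001, the design text's threshold, 38 genes were higher and 34 lower. All 72 were among the 99, as a stricter cut of the same p-values requires. The other 27 missed the threshold of 0.0001, and those named in the text were Pvrl1, Rrm1, Mvk, Dhcr7, Cenpa, Nusap1, Tacc3, Mad2l1, Mcm10, Nfib and Rnf26. With protein-coding genes only, 123 passed, 90 of them among the 99. Cma1 (unadjusted p = 0.0176) missed both adjusted thresholds, the p-value threshold of 0.0001 and the test of protein-coding genes only. With the inter-gene correlation preset to 0.05, 5 lists passed, and 5 with 0.1, in place of 9, because a higher correlation widens the test's error. Ranks, protein-coding genes only and adjustment for length and GC called 10 lists each, and 8, 9 and 9 of these were among the 9. No called list turned direction. Named genes could not, since every setting reused their deposited fold changes. Gene and list results that do not answer a comparison of their own were counted once per alternative setting, so a result can count several times. In that count 235 kept their side of the threshold, 13 lost and 4 gained a call. The seed differences stayed within the spread of the other orders in all settings. RLE and upper-quartile scaling, DESeq2 and voom fits, other low-count filters, another pseudocount, the replicate block and fits without each replicate were not run, since the columns of values per library were not used. No paired analysis was possible because the columns carry no sample numbers. Precision was not ranked between genes, and the depth behind each was not used here.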

Other observations

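The tests of length and GC, abundance, culture age, the host transcript, rows without a p-value, neighbouring genes and flanking chromosome were chosen only after the result was seen. Beyond the listed groups, further mitotic and chromatin genes were among the rises, and were picked after their values were seen. In the authors' deposited table, the kinetochore gene Cenpa (1.49), the spindle genes Nusap1 (1.54) and Tacc3 (1.36), the checkpoint gene Mad2l1 (1.24), the replication factor gene Mcm10 (1.40) and the histone chaperone gene Asf1b (1.55) rose; of these, Asf1b alone also passed the design text's p-value threshold of 0.0001. Ripk3, a kinase of necroptosis, rose by 1.12 and Ddc, the aromatic amino acid decarboxylase gene, by 1.54 in the authors' deposited table. Among the falls of the authors' deposited table were the transcription factor genes Satb1 (-1.36) and Nfib (-1.88, missing that threshold), Tnfsf4, which encodes OX40 ligand (-1.43), and the GTPase gene Gbp5 (-1.95).

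The cell cycle, histone and cholesterol synthesis genes were higher together in the miR-9 line. After a linear fit on gene length and GC content the 3 lists kept adjusted p-values of at most 2.87e-19, which argues against such a trend as the whole cause. Folds that rise with abundance stay open: ribosomal protein genes had a median of 0.15, below the lower quartile of the cell cycle list (0.80). Mitochondrially encoded mRNAs, however, had a median of 0.51 and an upper quartile of 0.82. Both lists were called higher, though the ribosomal call was lost at a preset correlation of 0.05, and abundance was not measured here. Different culture ages of the groups cannot be told apart from the genotype, because 0 of the 5 samples has a culture age of its own in the labels. The genotype itself also stays open, and no test here separated it from the growth state of the cultures.

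The rise of Gm25641 over the Mir9-1 hairpin was not seen for Gm3764, the host transcript of the hairpin on the opposite strand. The upper 95 percent bound of the log2 fold change of Gm3764 was 0.87, from the error its p-value implies under a normal test. That bound would argue against a rise of the whole host transcript only if the deposited folds were not shrunken towards 0. All rows of the authors' deposited table, scarce genes included, lay between -2.98 and 4.50, so shrinkage is not excluded. No conclusion on the host transcript is drawn from the bound. The depth behind Gm3764 was not used here, so a scarce host transcript was not told apart. A share of 0.648 of the orders of the same bases gave a difference as low as the miR-9-5p seed. That argues against a broad fall of predicted targets beyond -0.0527 in the deposited folds, while smaller shifts stay open. Shrinkage or the inclusion of scarce genes, for which no filter was applied here, could make a larger true fall appear smaller, so that stays open too. RNA made from the hairpin sequence at the modified allele itself was not tested, since no sequence or strand of the reads was used here.

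Rows without a p-value were not spread evenly over the gene lists, and lists that mark no cell type lacked it often too: extracellular proteases in 18 of 33 rows, chemotactic receptors in 8 of 23, integrins in 9 of 30, interferon response in 10 of 27 and mast cell cytokines in 6 of 22. Neutrophil and monocyte markers lacked it in 30 of 35 rows (85.7 percent) against 3 of 47 (6.38 percent) for lymphocyte, stromal and erythroid markers (two-sided Fisher's exact test, p = 5.91e-14), while dendritic cell and MHC class II genes (7 of 16, 43.8 percent) and basophil markers (3 of 12, 25 percent), in neither set, lay in between and eosinophil markers lacked it in 8 of 10. A filter on low abundance alone would need most lymphocyte, stromal and erythroid markers to be more abundant here than the neutrophil and monocyte markers. It stays open only because how abundant either set is in these cultures was not measured here. A second myeloid list without genes of any earlier list, an exclusion widened after a first run (25 of 32 rows, exact p = 3.30e-07), lacked a p-value in 23 of 30 rows against 3 of 26 for genes of foreign tissues (the same exact test, p = 8.89e-07). That repeats the first count in other genes. Such a filter alone would again need most of the foreign tissue genes to be more abundant here than the myeloid genes. The count does not show why the values are missing, so other myeloid cells in part of the libraries stay open as untested. The folds of the 30 neutrophil and monocyte rows without a p-value, S100a8 and Lyz2 among them, had a median of -0.02, from -0.70 to 0.13. Of these, 29 of 30 were negative, against 75.4 percent of all rows without a p-value, and 16 lay within 0.05 of 0.

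Called genes lay next to each other more often than random placements gave. Leaving out the Y chromosome, 7 neighbouring pairs moved the same way, against a mean of 0.200 and at most 3 in 10000 placements (permutation p = 0.0001, the smallest they can give). In 3 of the 7 pairs the gene models overlap, and the other pairs were Galc with Gpr65, Tpsb2 with Tpsg1, Gbp3 with Gbp2, and Pvrl1 with Rnf26. Sema4b, which fell by 1.03 on the log2 scale in the authors' deposited table, lies 681 kb from Mir9-3. Within 5 Mb of the 3 loci, with Gm25641 in neither group, 2 of 295 genes were called (Sema4b and Cks1b) against 96 of 23775 elsewhere (two-sided Fisher's exact test, p = 0.338).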
